A study of Sus scrofa with 32 samples.

How the data were processed

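The 32 arrays were single-colour Agilent scans of Cy3-labelled liver RNA read with Feature Extraction 10.7.3.1, and per the file headers each spot's processed signal was a background-subtracted fluorescence intensity. Every array held 45220 spots, of which 43803 were not controls, and 50 probes were spotted more than once. Control spots and spots the scanner software called outliers were left out. The value used was the log2 of the processed signal minus the 75th percentile of that array, so a level of 0 is the signal of a spot at that percentile, and spots of one probe were averaged on the log2 scale. The authors also deposited a table of log2 values made with Partek (version not given in the sources used here). Its columns had medians from 5.148 to 5.153 and 1 shared maximum of 18.47, the mark of quantile normalization, and it correlated with the log2 processed signal at 0.993 to 1.00 across probes of an array. That table served as an alternative source of values.

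Probes were named only through the RefSeq accession in the array design, matched without versions to the pig annotation Sscrofa11.1. Of 43603 probes, 2683 matched and gave 1904 gene symbols. The match covered 2476 of 2553 curated and 206 of 686 predicted RefSeq transcripts, and 0 of 4762 Ensembl transcript probes. The 40920 other probes kept their array name, so counts over all features run mostly over probes without a symbol. A probe was tested when it was well above background on at least 3 of the 4 arrays of at least 1 group, which 29361 probes were. For a symbol with several such probes, the one with the highest mean stood for the gene. Other probes of a named gene are given where their call differed, and further probes of AFP, IGF2 and DLK1 had the other sign in some comparisons without passing there. This left 28673 features, 1596 with a symbol, and 251 missing values in 248 of them. Features with a missing value were left out of the set tests, which used 28425. Where the lower group was not well above background on any array, the fold is given as a lower bound, "at least", computed against the background limit. No genome position is given.

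One mean for each of the 8 groups of day and fetus type was fitted with limma 3.58.1 (R 4.3.3) over all 32 arrays, with 24 residual degrees of freedom, so that all groups shared one estimate of the spread. All tests were two-sided. P-values were adjusted by Benjamini-Hochberg over all features of a contrast. Between days of the control course a gene passed at an adjusted p under 0.05 and a change of at least 2-fold, and between runts and controls at an adjusted p under 0.05. Standard errors (SE) are those of the fit. The mean runt effect over the 4 days and the difference of the runt effect between days (an F-test) came from the same fit. Exact tests of list scores used all 70 ways to label 8 arrays, and the smallest p they can give is 0.0286.

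A set of 36 gene lists was fixed before the data were examined. They cover plasma proteins, complement, acute phase response, fetal and oncofetal liver genes, liver transcription factors, urea cycle, amino acid catabolism, gluconeogenesis, glycogen metabolism, glycolysis, fatty acid oxidation, fatty acid synthesis, cholesterol synthesis, bile acids, xenobiotic and retinoid metabolism, the IGF and growth hormone axis, glucocorticoid responsive genes, hypoxia, amino acid and unfolded protein stress, immediate early and heat shock genes, oxidative phosphorylation, antioxidant and iron genes, and cell cycle. The other lists hold markers of erythroid cells, blood stem and progenitor cells, megakaryocytes and platelets, granulocytes, Kupffer cells and monocytes, lymphocytes, endothelial cells, stellate cells, bile duct, pancreas, muscle, and gut, kidney, gonad and adrenal, with 1 list of X-inactivation and Y-linked genes. Of 1265 listed symbols 397 were on the array and 359 were measured. The 31 lists with at least 5 measured members were tested with camera at a preset correlation between genes of 0.01, which asks whether a list moved against all other genes. The X-inactivation and Y-linked list had 0 measured members and gave no value. Members were also counted with p adjusted over the list alone. The granulocyte list first held ELA2 through an alias of a pancreatic elastase, CELA2A. The alias was removed after the data had been seen, and both versions are given. Some lists share members. HP and LYZ of the granulocyte list are also in liver or macrophage lists, TFRC is in the erythroid list and the antioxidant and iron list, and NR1I2 is in the transcription factor list and the xenobiotic list.

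Named genes followed a rule set before the data were examined. In each comparison they were the 5 largest rises and 5 largest falls among genes that passed, whose 4 arrays of one group all lay above the other 4 and whose higher group was well above background on all 4 arrays. For the mean runt effect the same sign was required on all 4 days, and for the difference between days the 10 smallest p were taken. Where fewer than 3 genes passed, the 5 with the smallest p were also named as not passing. This was read as fewer than 3 genes with a symbol at day 110, a reading chosen after the counts were seen. For each list called by camera up to 4 members were added, together with a fixed panel of 15 genes, of which 9 were measured, among them ALB, AFP, IGF1, IGF2, IGFBP2, DLK1, CYP7A1 and APOA4. Some genes that the rule names are not reported here.

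Per the labels, each control and runt pair of a day were littermates from 4 distinct gilts, but the labels do not say that the replicate number marks the pair. After group means were removed, the 2 fetuses of one number correlated across genes above 0.1 in 4, 3, 2 and 4 of 4 pairs at days 37, 50, 70 and 110 (ranges 0.13 to 0.42, -0.09 to 0.42, -0.01 to 0.31 and 0.13 to 0.19). The own number was the best match for 3, 2, 1 and 2 of the 4 runts. With the slide set removed as well, 2, 3, 1 and 2 of the 4 pairs stayed above 0.1, and 3 of the 4 pairs of each day lay within 1 slide set. The numbers were taken to pair at days 37 and 110 because every pair there lay above 0.1 before the slide set was removed, so the pairing rests on the correlation alone and shared slides were not excluded as its source, and a fit with the replicate number as a block is given as an alternative. Per the file headers, 9 slides carried the arrays. Slides 1 to 3 and 5 to 8 held 4 arrays of 4 different days, slide 4 held 3 arrays (days 37, 70 and 110), slide 9 held day 50 runt replicate 1 alone and was scanned on another day, and control and runt of one day never shared a slide. Slides 1 to 3 parted from slides 4 to 9 on the component axis with the next largest variance after the axis that ordered the days, but for 1 array of slide 7 that lay among slides 1 to 3. A block for this slide set and fits within each part were added after the data had been seen. They give each group 1 to 3 arrays, and a lone array is assumed to vary like the other groups.

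Background correction by normexp is usually run on mean signals, which the files used here do not hold. It was run on the median signal and median local background of all spots with an offset of 50. A few spots with a local background far above their signal distorted this correction on 6 runt arrays, so versions that set such spots aside were added after the data had been seen. The fit was tested on simulated values of 28673 genes with the observed spread, with shifts added to 200 of them.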

Results

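Gene expression was measured in the livers of pig fetuses at gestational days 37, 50, 70 and 110, close to term. At each day 4 control fetuses were compared with 4 runts, the small littermates that arise in a crowded uterus, for 8 groups and 32 arrays. The uterus was crowded by removing 1 horn and ovary of each gilt. Between 51.3% and 69.4% of the spots of an array were well above background (median 62.0%), no spot was saturated, and the signal at the 75th percentile ran from 177 to 460 intensity units. Replicate arrays of a group correlated at 0.961 to 0.985 across probes. The number of arrays, 4 per group, limits the precision of each value. The component with the most variance, 45.6%, ordered the gestational days. Each day also had its own array position on the slides, position 1, 2, 3 and 4 for days 37, 50, 70 and 110. The lone array of slide 9, a day 50 runt, was at position 1. Day and position therefore cannot be told apart in the control comparisons between days. The next component, with 8.33%, parted slides 1 to 3 from slides 4 to 9, but for 1 array of slide 7 (day 37 runt replicate 2) that lay among slides 1 to 3. Both slide sets hold control and runt arrays.

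**Figure D1:**
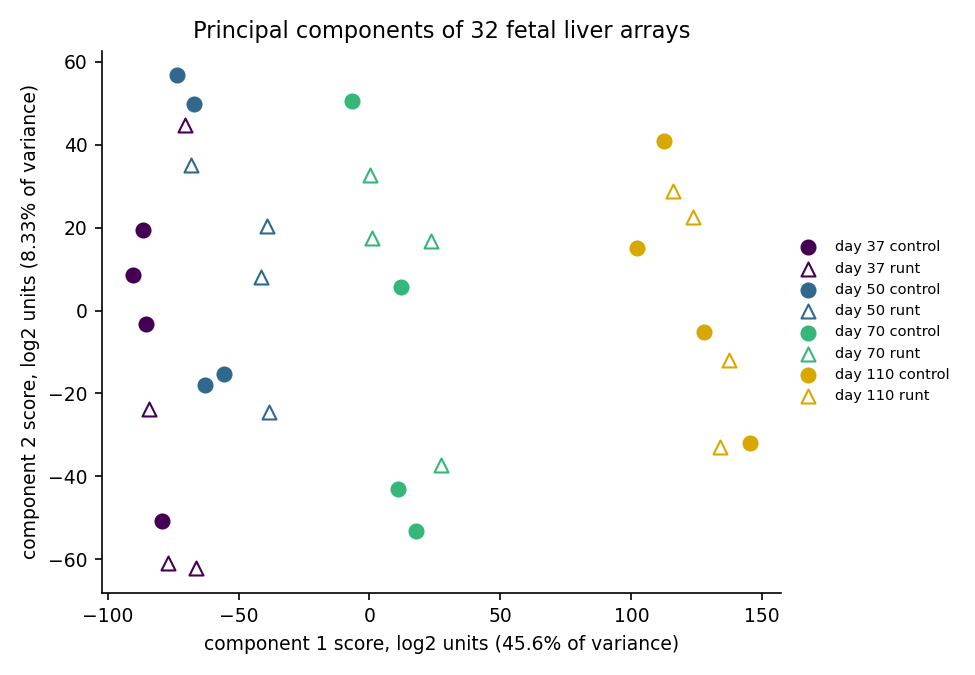
Scores of the 32 arrays on the principal components with the most variance, in log2 units, with colour for gestational day and symbol for control or runt. Component 1 (45.6% of variance) orders the days and component 2 (8.33%) follows the slide set but for 1 array.

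The control fetuses addressed how the liver's gene expression changes over gestation. From day 37 to day 50 a xenobiotic receptor and a growth factor binding protein were among the genes that rose. NR1I2 (NM_001038005), the xenobiotic-sensing pregnane X receptor, rose from a level not above background, -7.15 ± 0.35 (SD, n = 4), to -3.91 ± 0.67, at least 2.07-fold (adjusted p = 5.15e-05). IGFBP2 (NM_214003), a binding protein for insulin-like growth factors, rose 5.65-fold from 2.02 ± 0.47 to 4.52 ± 0.13 (log2 change 2.50, SE 0.46, adjusted p = 0.00169). The phosphate transporter SLC34A1 (2.27, adjusted p = 0.00894, above background on 1 of 4 arrays at day 37), the angiotensin-cleaving peptidase ENPEP (2.27, adjusted p = 0.00125) and lysozyme, LYZ (2.17, adjusted p = 0.0202), rose as well. The largest falls were in PLA2G1B, the pancreatic phospholipase A2 (-2.59, adjusted p = 0.00228), TLDC2 (-2.48, adjusted p = 0.00166) and the collagen chain COL5A3 (-2.07, adjusted p = 0.00426). The transcriptional coregulator CITED1 (-1.57, adjusted p = 0.0236) and the natural killer cell receptor KLRK1 (-1.31, adjusted p = 0.00419) fell less.

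Over all features 979 passed between days 37 and 50, 888 higher and 91 lower at day 50, of which 27 had a symbol (19 higher and 8 lower). By camera the 14 granulocyte genes all lay above 0 (median 0.69, adjusted p = 0.0361, adjusted p = 0.715 with an estimated correlation), with LYZ the 1 member that rose and 13 that did not pass. The plasma protein list rose (median 0.29, 19 of 24 above 0, adjusted p = 0.0361, adjusted p = 0.715 with an estimated correlation) although 0 of its 24 members passed in limma, also 0 adjusted over the list alone. VTN, vitronectin, had the smallest p among them (0.89, SE 0.15, adjusted p = 0.000913, under 2-fold). The glycolysis list fell (median -0.50, 6 of 8 below 0, adjusted p = 0.0361, adjusted p = 0.649 with an estimated correlation), again with 0 members past both thresholds, also adjusted over the list alone. GPI, glucose phosphate isomerase, was at -0.68 (adjusted p = 0.0217, under 2-fold). In the panel ALB, serum albumin (1.36, adjusted p = 0.163), AFP, its fetal relative (0.12, adjusted p = 0.874), and IGF1 (-0.04, adjusted p = 0.947) did not pass. Nor did IGF2 (0.15, adjusted p = 0.722), DLK1 (-0.33) or APOA4 (0.41), and CYP7A1 was below background on both days. With slide as a block the direction of these lists held. Within slides 1 to 3 the count of genes was 0 and within slides 4 to 9 it was 152. With the older granulocyte list 0 lists were called, and without day 37 control replicate 3 also 0.

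From day 50 to day 70 genes of drug metabolism and detoxification were among the largest rises. CYP2C42 (NM_001167835), a cytochrome P450, rose 18.2-fold (log2 change 4.19, SE 0.92, adjusted p = 0.00202), and NR1I2 rose a further 15.6-fold to 0.05 ± 1.02 (3.97, SE 0.42, adjusted p = 1.03e-06). The glutathione transferase GSTA1 (3.12, adjusted p = 0.0173, above background on 3 of 4 arrays at day 50), the guidance factor NTN1 (3.11, adjusted p = 0.000160) and the lipoxygenase ALOX15 (2.67, adjusted p = 0.00127) rose too. PDZK1IP1, a membrane protein of epithelia (-2.73, adjusted p = 0.000435), the oestrogen sulfotransferase SULT1E1 (-2.59, adjusted p = 0.0106) and TLDC2 (at least 4.97-fold lower, adjusted p = 0.000314) fell. So did the organic anion carrier SLCO3A1 (-2.53, adjusted p = 0.0127) and KLRK1 (-2.46, adjusted p = 1.54e-06). SULT1E1 was above background on 3 and SLCO3A1 on 2 of the 4 day 70 arrays. IGFBP2 rose again (2.31, adjusted p = 0.000873).

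Liver function lists rose between days 50 and 70 while proliferation and red cell lists fell. The liver transcription factor list rose (median 0.59, 12 of 13 above 0, adjusted p = 2.33e-05, adjusted p = 0.00489 with an estimated correlation), with NR1I2 and the related receptor NR1I3 (2.01, adjusted p = 0.000924) the 2 members that passed. The xenobiotic list rose (median 0.46, 19 of 24 above 0, adjusted p = 0.00338, adjusted p = 0.174 with an estimated correlation), with 5 members higher, 1 lower and 18 that did not pass. The cholesterol synthesis list rose (median 0.68, 6 of 6 above 0, adjusted p = 0.00163, adjusted p = 0.174 with an estimated correlation). Plasma proteins (median 0.43, 22 of 24 above 0, adjusted p = 0.000118, adjusted p = 0.365 with an estimated correlation) rose without a single member past 2-fold, the coagulation factor F10 being at 0.83 (adjusted p = 0.000174). The complement list rose (median 0.47, 15 of 17 above 0, adjusted p = 0.0116, adjusted p = 0.354 with an estimated correlation), with C6 (2.18, adjusted p = 0.0191, above background on 2 of 4 arrays at day 50) and the lectin MBL1 (1.15, adjusted p = 0.00734) higher and 15 not passing. Another probe of C6 was at 0.69 (adjusted p = 0.169) and did not pass. In the acute phase list (median 0.44, 10 of 11 above 0, adjusted p = 0.0319, adjusted p = 0.345 with an estimated correlation) the endotoxin receptor CD14 rose (1.65, adjusted p = 2.80e-05) and 10 did not pass.

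Markers of immune and supporting cells rose over the same interval. Granulocyte genes (median 1.16, 13 of 14 above 0, adjusted p = 0.00181, adjusted p = 0.365 with an estimated correlation) had 5 members higher and 7 adjusted over the list alone. Among them were the antimicrobial peptide PR39 (1.96), lactoferrin, LTF (1.95), PGLYRP1 (1.76) and the gelatinase MMP9 (1.75). The Kupffer cell list rose (median 0.38, 17 of 21 above 0, adjusted p = 0.00180, adjusted p = 0.345 with an estimated correlation), 5 members higher and 16 not passing. The macrophage adhesion receptor SIGLEC1 (at least 3.07-fold) and the class II antigen genes SLA-DQA1 (1.76) and SLA-DRA (1.72, another probe at 1.05) were among the 5. The lymphocyte list rose (median 0.87, 14 of 16 above 0, adjusted p = 0.0132, adjusted p = 0.174 with an estimated correlation). Among genes well above background on all 32 arrays its direction against other genes turned (median 0.18, adjusted p = 0.889). The T cell receptor subunits CD3G (at least 1.04-fold, above background on 2 of 4 arrays at day 70) and CD247 (1.55) and the pre-B cell gene VPREB1 (1.69) were among its 4 higher members, and KLRK1 was the 1 lower. Another probe of CD247 was at 0.54 (adjusted p = 0.0936) and did not pass. Endothelial genes (median 0.60, 11 of 13 above 0, adjusted p = 0.00325, adjusted p = 0.174 with an estimated correlation) rose with 0 members past 2-fold in limma, nitric oxide synthase NOS3 being at 0.96 (adjusted p = 0.000207). Stellate cell and fibroblast genes (median 0.42, 15 of 17 above 0, adjusted p = 0.0214, adjusted p = 0.370 with an estimated correlation) had 3 higher members, RGS5 (1.46), COL5A1 (1.41) and IGFBP3 (1.10). The cell cycle list fell (median -0.57, 10 of 10 below 0, adjusted p = 0.00991, adjusted p = 0.370 with an estimated correlation), with the mitotic kinase AURKA at -0.97 (adjusted p = 0.00455, under 2-fold) and 0 members past 2-fold. The erythroid list fell (median -0.66, 5 of 5 below 0, adjusted p = 0.0376, adjusted p = 0.365 with an estimated correlation), with embryonic globin HBE1 the 1 member that passed (-1.53, adjusted p = 0.00239). In all 2204 features passed, 811 higher and 1393 lower at day 70, including 117 with a symbol (87 higher and 30 lower). Adjusted over the list alone the counts of members differed from those over all genes only for granulocytes. The share of higher features was 36.8% and turned to 62.6% with normexp and 51.1% with the stricter background filter, so this balance depends on the processing. The count was 1 within slides 1 to 3 and 498 within slides 4 to 9.

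From day 70 to day 110 complement transcripts and those of GSTA1 and the growth hormone receptor rose and red cell and cell cycle transcripts fell. C6 (NM_001097449), a component of the membrane attack complex, rose 99.6-fold (log2 change 6.64, SE 0.67, adjusted p = 1.52e-08, above background on 3 of 4 arrays at day 70), and by 5.26 at another probe. GSTA1 rose 86.5-fold (6.43, SE 0.94, adjusted p = 6.49e-06), and the complement regulator C4BPA 30.2-fold (4.92, SE 1.18, adjusted p = 0.00232). The peptide transporter SLC15A1 rose 28.1-fold (4.81, adjusted p = 3.18e-07), and GHR (NM_214254), the growth hormone receptor, 24.9-fold (4.64, SE 0.29, adjusted p = 1.77e-11, above background on 2 of 4 arrays at day 70). HBE1 fell 24.9-fold (-4.64, SE 0.34, adjusted p = 1.35e-10). The metalloreductase STEAP1 (-4.18), slow troponin I, TNNI1 (-4.11), and the calcium-activated potassium channels KCNN4 (-3.98) and KCNN3 (-3.59) fell as well, at adjusted p from 4.53e-06 to 5.25e-11. STEAP1 and KCNN3 were above background on 3 and 2 of the 4 day 110 arrays.

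All 10 cell cycle genes fell between days 70 and 110 (median -2.71, adjusted p = 5.73e-18, adjusted p = 0.0236 with an estimated correlation), led by CCNB1 (-3.06), CDK1 (-2.98), the topoisomerase TOP2A (-2.84) and BIRC5 (-2.82). All 5 erythroid genes fell (median -3.18, adjusted p = 1.07e-08, adjusted p = 0.0236 with an estimated correlation), with the Rh blood group gene RHCE at -3.45 and the erythropoietin receptor, EPOR, at -3.18. The megakaryocyte and platelet list fell (median -1.60, 5 lower and 1 higher of 6, adjusted p = 0.000649, adjusted p = 0.0641 with an estimated correlation), with the integrins ITGB3 (-1.94) and ITGA2B (-1.52), PPBP (-1.91) and CD9 (-1.68). Granulocyte genes fell back (median -1.40, 13 of 14 below 0, adjusted p = 0.000688, adjusted p = 0.388 with an estimated correlation), 6 lower over all genes and 8 adjusted over the list alone, with PGLYRP1 (-2.37), PR39 (-2.30), FCN1 (-2.15) and LTF (-2.03). In the antioxidant and iron list (median -0.37, 12 of 17 below 0, adjusted p = 0.0297, adjusted p = 0.228 with an estimated correlation) the transferrin receptor, TFRC (-2.80), and thioredoxin, TXN (-1.195, another probe at -0.94 and under 2-fold), fell and 15 did not pass.

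Complement genes rose (median 1.05, 16 of 17 above 0, adjusted p = 6.52e-05, adjusted p = 0.0641 with an estimated correlation), 9 passing and 8 not. C7 (3.17, above background on 2 of 4 arrays at day 70) and the protease MASP2 (2.53) were also among them. Acute phase genes rose (median 0.61, 11 of 11 above 0, adjusted p = 0.00161, adjusted p = 0.0641 with an estimated correlation), with 4 passing. They were CD14 (2.30), serum amyloid SAA3 (2.23), C-reactive protein, CRP (1.61), and the immunoglobulin transporter PIGR (at least 1.196-fold, above background on 3 arrays at day 110). The liver transcription factor list rose (median 0.62, 12 of 13 above 0, adjusted p = 0.00132, adjusted p = 0.0305 with an estimated correlation) with NR1I2 (3.27), GATA4 (1.32) and PROX1 (1.10) past 2-fold. Among glucocorticoid responsive genes (median 0.52, 5 of 7 above 0, adjusted p = 0.0123, adjusted p = 0.0641 with an estimated correlation) 3 rose, the transcription factor KLF9 (at least 3.05-fold), the lipase inhibitor ANGPTL4 (1.94) and the cortisol-regenerating enzyme HSD11B1 (1.58). Gluconeogenesis genes rose (median 0.59, 5 of 6 above 0, adjusted p = 0.0388, adjusted p = 0.228 with an estimated correlation), with pyruvate carboxylase, PC, the 1 member that passed (1.07, adjusted p = 2.41e-05). The Kupffer cell list rose (median 0.70, 13 of 21 above 0, adjusted p = 0.00726, adjusted p = 0.386 with an estimated correlation) with 7 higher and 2 lower members, and 8 higher adjusted over the list alone. CD14 (2.30), SLA-DRA (1.97), SLA-DQA1 (1.80) and SLA-DQB1 (1.69) were the highest. The endothelial list rose (median 0.56, 12 of 13 above 0, adjusted p = 0.00489, adjusted p = 0.125 with an estimated correlation). The Fc receptor FCGR2B (2.69) and caveolin, CAV1 (1.69), were among 3 higher members, and the water channel AQP1 (-3.01, also a red cell protein, above background on 3 arrays at day 110) was lower. CYP7A1, the rate-limiting enzyme of bile acid synthesis, passed (adjusted p = 0.000541), but it was above background on 1 of 4 arrays at day 110 and 0 at day 70, so no fold is given. IGFBP2 did not pass (1.14, adjusted p = 0.0652). In all 3565 features passed, 1544 higher and 2021 lower at day 110, including 279 with a symbol (134 higher and 145 lower). In the other called lists the counts of members adjusted over the list alone equalled those over all genes. The count was 1827 within slides 1 to 3 and 1545 with normexp.

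Over the whole course, from day 37 to day 110, GSTA1 rose by 10.49 on the log2 scale (SE 0.94, adjusted p = 4.81e-10, above background on 2 of 4 arrays at day 37). NR1I2 rose at least 312-fold (adjusted p = 3.05e-16) and C6 at least 320.2-fold (adjusted p = 3.94e-12), while another probe of C6 rose by less, 5.88 on the log2 scale (adjusted p = 8.15e-13). CYP2E1 (NM_214421), the ethanol-oxidising P450, rose 263-fold (8.04, SE 1.88, adjusted p = 0.000786), and NTN1 87.0-fold (6.44, above background on 2 of 4 arrays at day 37). PLA2G1B fell 119-fold (-6.90, SE 0.49), CITED1 114-fold (-6.83, SE 0.43, above background on 1 of 4 arrays at day 110) and HBE1 75.7-fold (-6.24, SE 0.34), each at an adjusted p under 0.05. TLDC2 fell at least 42.3-fold and SPMI, the seminal plasma motility inhibitor, at least 15.7-fold (adjusted p = 2.59e-05). In the panel IGFBP2 rose 61.7-fold to 7.96 ± 0.28 (adjusted p = 2.71e-11), APOA4 by 3.58 (adjusted p = 0.000274), ALB by 1.39 (SE 0.59, adjusted p = 0.0493) and CYP7A1 passed (adjusted p = 0.000110), with no fold given because it was above background on 1 of 4 arrays at day 110 and 0 at day 37. DLK1, a growth regulator of hepatoblasts, was at -0.96 (adjusted p = 0.0151, under 2-fold), but another of its probes was at -4.72 and passed (adjusted p = 2.69e-08). AFP (-0.40, adjusted p = 0.269), IGF1 (0.22, adjusted p = 0.441) and IGF2 (0.14, adjusted p = 0.556) did not pass. Other probes of CYP2E1, CD14, HSD11B1, SLA-DRA, SLA-DQA1 and ALB also passed, at 7.06, 4.99, 3.17, 3.63, 3.60 and 2.07. AFP was at 9.42, 9.54, 9.57 and 9.02 in controls of the successive days, and IGF2 at 8.42, 8.57, 8.75 and 8.56.

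**Figure D2:**
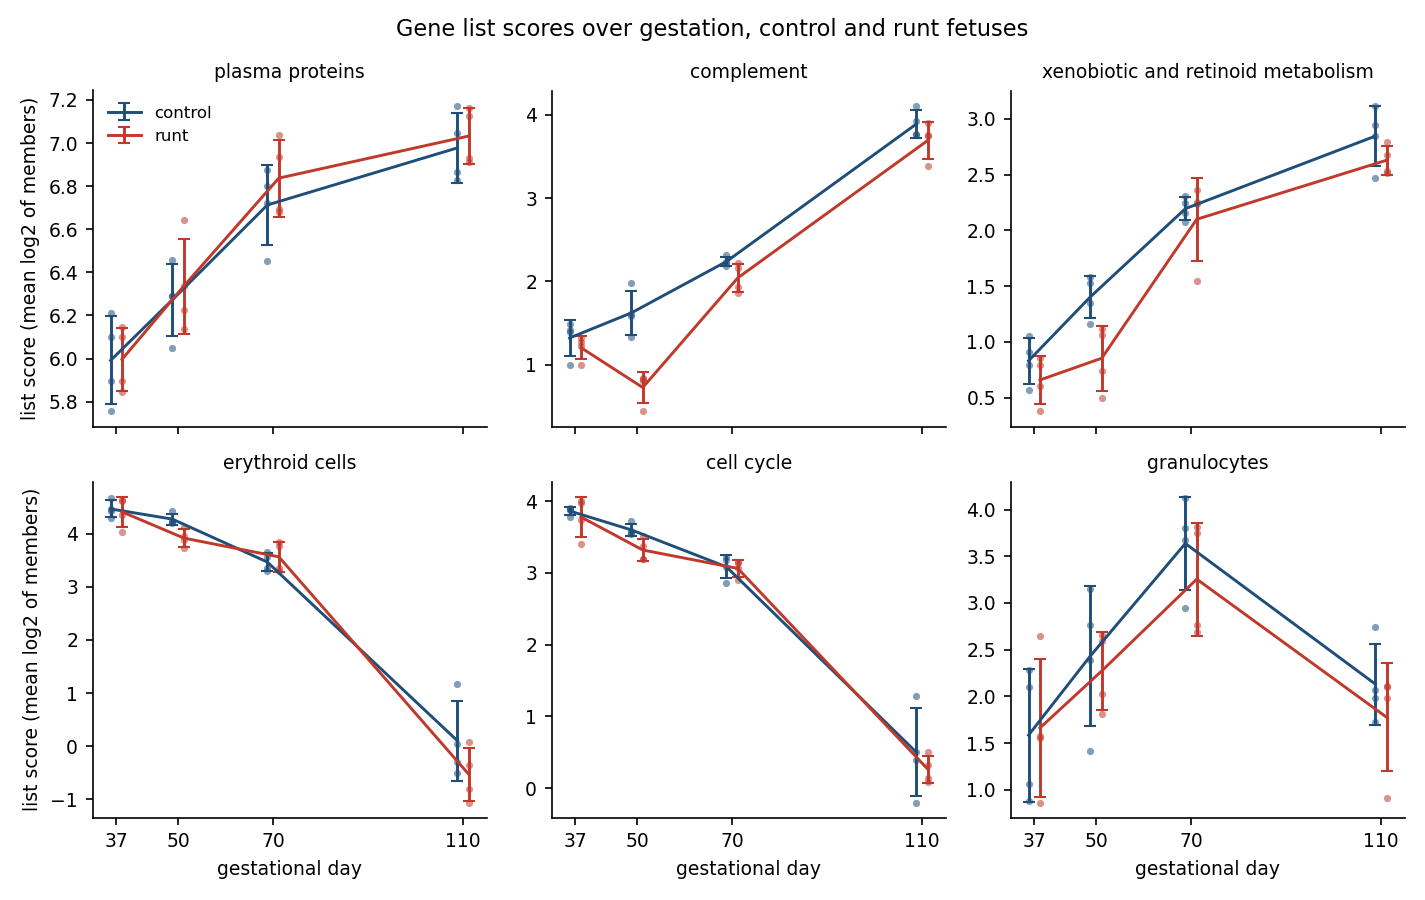
Mean log2 level of the members of 6 gene lists by gestational day, control and runt fetuses, with each array as a point and mean ± SD (n = 4) as a line. In controls the complement score rose from 1.32 to 3.89 and the erythroid score fell from 4.47 to 0.10 between days 37 and 110, while the granulocyte score was highest at day 70 (3.64).

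All 17 complement genes lay above 0 from day 37 to day 110 (median 2.00, adjusted p = 2.60e-06, adjusted p = 0.0471 with an estimated correlation), and 14 rose, including C4BPA (5.77), C7 (at least 9.65-fold) and MBL1 (2.49). Plasma proteins rose (median 0.85, 20 of 24 above 0, adjusted p = 6.30e-05, adjusted p = 0.249 with an estimated correlation) with 10 passing, among them the coagulation factors F7 (2.56, above background on 3 arrays at day 37), F10 (1.95) and F9 (1.80). The acute phase list (median 1.80, 10 of 11 above 0, adjusted p = 0.00069, adjusted p = 0.0471 with an estimated correlation) had 7 members higher. SAA3 (4.95), CD14 (4.25), LBP, the lipopolysaccharide binding protein (2.87), and PIGR (at least 1.498-fold) were examples. Liver transcription factors rose (median 1.19, 13 of 13 above 0, adjusted p = 2.60e-06, adjusted p = 0.00303 with an estimated correlation), 8 passing. Examples were NR1I3 (4.14), GATA4 (1.91) and the metabolic coactivator PPARGC1A (1.81). Gluconeogenesis genes (median 1.39, 5 of 6 above 0, adjusted p = 0.0352, adjusted p = 0.174 with an estimated correlation) had 4 members higher and 1 lower. FBP1 (1.75) and the glucocorticoid receptor NR3C1 (1.68) rose and MDH1 fell (-1.14). The xenobiotic list (median 0.40, 16 of 24 above 0, adjusted p = 0.0496, adjusted p = 0.260 with an estimated correlation) had 9 higher and 4 lower members, with the steroid sulfotransferase SULT2A1 at 5.81. Glucocorticoid responsive genes rose (median 1.04, 6 of 7 above 0, adjusted p = 0.0461, adjusted p = 0.148 with an estimated correlation). KLF9 (at least 3.83-fold) and HSD11B1 (2.23) were among 4 higher members, and the cortisol carrier SERPINA6 was lower (-1.32). The antioxidant and iron list fell (median -0.27, 12 of 17 below 0, adjusted p = 0.0487, adjusted p = 0.245 with an estimated correlation), with 6 members lower. They included TFRC (-3.97), TXN (-1.89) and GPX1 (-1.79), while the iron hormone HAMP was higher (1.80).

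All 10 cell cycle genes fell over the course (median -3.30, adjusted p = 3.77e-11, adjusted p = 0.0471 with an estimated correlation), with AURKA (-4.22, above background on 3 arrays at day 110), CCNB1 (-4.20), CDK1 (-3.73) and BIRC5 (-3.43) lowest. All 5 erythroid genes fell (median -3.97, adjusted p = 7.67e-06, adjusted p = 0.0471 with an estimated correlation), with EPOR at -4.19 and RHCE at -3.88. Megakaryocyte genes fell (median -2.12, adjusted p = 0.0112, adjusted p = 0.148 with an estimated correlation), 5 of 6 lower. ITGB3 (-2.76), PPBP (-2.21) and SELP (-2.16) fell most, and thromboxane synthase, TBXAS1, was higher (2.28, above background on 2 arrays at day 37). The Kupffer cell list rose (median 1.13, 18 of 21 above 0, adjusted p = 0.000135, adjusted p = 0.148 with an estimated correlation), 11 higher and 2 lower, with SLA-DRA (4.37), SLA-DQA1 (4.26) and SLA-DQB1 (3.66). Endothelial genes rose (median 1.45, 12 of 13 above 0, adjusted p = 7.54e-05, adjusted p = 0.0471 with an estimated correlation), 10 higher and AQP1 lower (-3.65), with FCGR2B (4.18), CAV1 (3.34) and the ficolin FCN2 (2.54). The lymphocyte list rose (median 1.404, 12 of 16 above 0, adjusted p = 0.0196, adjusted p = 0.0833 with an estimated correlation), 8 higher, 9 adjusted over the list alone, and KLRK1 lower (-3.59). The T cell genes CD3G (at least 4.56-fold), CD8A (at least 2.37-fold) and CCR7 (at least 4.31-fold) rose. Elsewhere among the called lists the counts adjusted over the list alone equalled those over all genes. Among genes above background on all 32 arrays the lymphocyte median was -0.32 (adjusted p = 0.776).

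The other lists were not called between days 37 and 110. The IGF and growth hormone axis (median 1.199, adjusted p = 0.107) held 8 members that rose and 2 that fell. Cholesterol synthesis was at 0.73 (adjusted p = 0.0608), stellate cells at 0.79 (adjusted p = 0.0643, 5 higher and 1 lower) and granulocytes at 0.51 (adjusted p = 0.489, 0 of 14 passing). Glycolysis (-0.56, adjusted p = 0.336), gut, kidney, gonad and adrenal genes (-0.92, adjusted p = 0.240), pancreas genes (-0.71, adjusted p = 0.784) and bile duct genes (0.37, adjusted p = 0.294) were not called either. Nor were muscle genes (0.22, adjusted p = 0.489), immediate early and heat shock genes (0.37, adjusted p = 0.430) or stress genes (-0.34, adjusted p = 0.728). Medians within 0.1 of 0 were seen for fetal and oncofetal genes (0.09), amino acid catabolism (0.01), fatty acid oxidation (-0.04), fatty acid synthesis (-0.04), hypoxia (-0.03) and oxidative phosphorylation (-0.09). In all of these but amino acid catabolism the mean had the other sign. The lists too small to test had medians of 0.09 for the urea cycle (4 members, 1 higher and 1 lower), 0.49 for glycogen (3, 1 higher), 0.21 for bile acids (4, 1 higher) and -0.54 for blood stem and progenitor cells (4, 1 higher and 2 lower). In all 8402 features passed, 4301 higher and 4101 lower at day 110, including 579 with a symbol (332 higher and 247 lower). The count was 5310 within slides 1 to 3 and 4018 with normexp.

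Runts were compared with control littermates at each day to find how poor growth alters the liver. At day 37 albumin had the smallest p among named genes, ALB (NM_001005208) being at 3.68 ± 1.54 (SD, n = 4) in runts and 6.22 ± 0.66 in controls, a log2 difference of -2.54 (SE 0.59, adjusted p = 0.777) that did not pass. MAL2 (-0.93), COL5A3 (-1.47, above background on 2 runt arrays) and GDF9 (0.51) did not pass (adjusted p = 1 each). Nor did the bile duct regulator SOX9 (adjusted p = 1), which was above background on 1 of the 8 arrays. In limma 0 features passed at day 37, with a lowest adjusted p of 0.116. An unadjusted limma p under 0.05 was reached by 715 features, fewer than the 1434 that chance alone would give. Adjusted over the list alone ALB was lower among the plasma proteins. No list was called, liver transcription factors coming nearest (median 0.16, adjusted p = 0.0517). With slide as a block 2 lists were called and within slides 4 to 9 there were 3.

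At day 50 complement transcripts and LBP mRNA were lower in runts. LBP (NM_001128435), which hands bacterial lipopolysaccharide to its receptor, was lower 5.41-fold, at -2.37 ± 0.68 in runts and 0.07 ± 0.38 in controls (log2 difference -2.44, SE 0.38, adjusted p = 0.00464). The complement list fell (median -0.92, 15 of 17 below 0, adjusted p = 6.89e-12, adjusted p = 0.00589 with an estimated correlation), and 10 of its 17 members were lower adjusted over the list alone while 0 passed over all genes. Among these 10 were C8B (-1.93, SE 0.41), C3, the central component (-1.78, from 6.08 ± 0.78 in controls to 4.30 ± 1.00 in runts), C1S (-1.71), C4A (-1.69, above background on 2 runt arrays), C2 (-1.57), MASP2 (-1.53) and MBL1 (-1.45, adjusted p = 0.0565). C7 (0.46) and C8G (0.48) lay above 0. The exact test of the complement score gave p = 0.0286, the smallest it can give, and adjusted p = 0.148, and no list passed the adjusted exact test at any day. NR1I2 was at least 1.85-fold lower in runts, where it was not above background (adjusted p = 0.0209), and the membrane protein TMEM87A was higher (0.69, SE 0.13, adjusted p = 0.0209). With normexp as first run both turned, NR1I2 to 0.94 (adjusted p = 0.0420) and TMEM87A to -0.03.

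**Figure D3:**
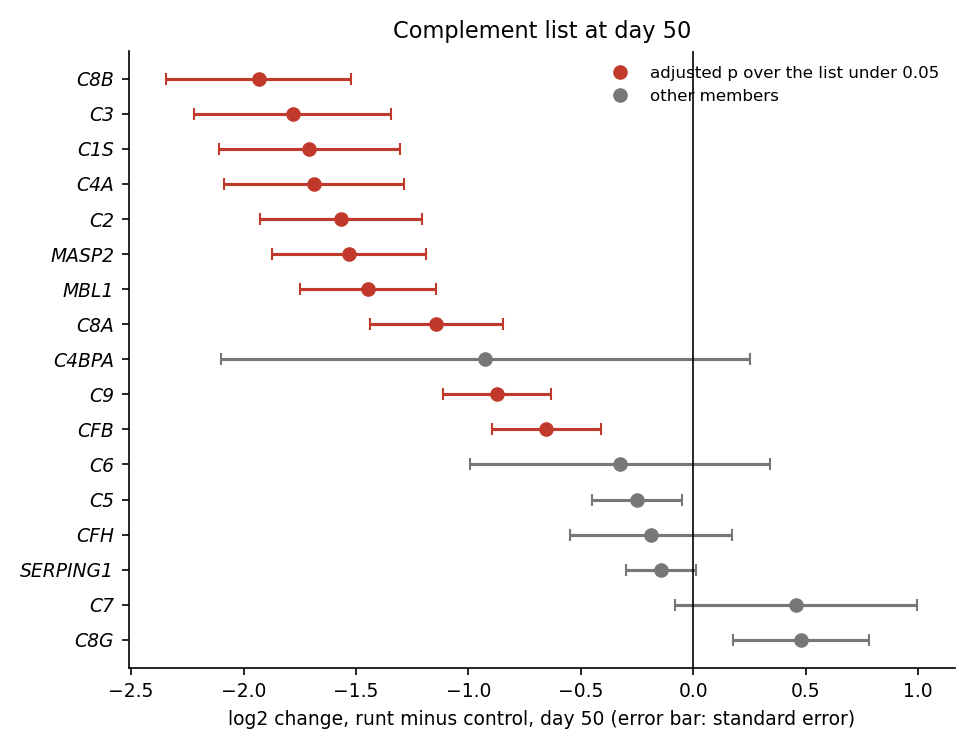
Log2 difference between runts and controls at day 50 for the 17 measured complement genes, with standard errors and red for an adjusted p over the list alone under 0.05. The list median was -0.92, 15 genes lay below 0, and 10 passed over the list alone.

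The plasma protein list was not called at day 50 (median 0.18, adjusted p = 0.0784), although ALB was at -2.73 (SE 0.59, adjusted p = 0.0663) and did not pass. Another probe of ALB was at -3.75 and passed (adjusted p = 0.0110). The level of the main probe was 4.85 ± 1.11 in runts and 7.57 ± 0.41 in controls. The acute phase list, which holds LBP, had a median of 0.03 and a mean of -0.33 (adjusted p = 0.286), with 1 member higher and 3 lower adjusted over the list alone. The xenobiotic list fell (median -0.32, 15 of 24 below 0, adjusted p = 0.0132, adjusted p = 0.453 with an estimated correlation) with NR1I2 the 1 member that passed and 5 adjusted over the list alone. Kupffer cell genes fell (median -0.22, 17 of 21 below 0, adjusted p = 0.00614, adjusted p = 0.453 with an estimated correlation) with 0 passing in limma and the macrophage marker AIF1 at -0.47 (adjusted p = 0.345, but 0.14 at another probe). The cell cycle list fell (median -0.30, 10 of 10 below 0, adjusted p = 0.0146, adjusted p = 0.575 with an estimated correlation), TOP2A being at -0.36 (adjusted p = 0.729). Amino acid catabolism fell (median -0.23, 6 of 7 below 0, adjusted p = 0.0408, adjusted p = 0.453 with an estimated correlation), with CTH, cystathionine gamma-lyase, at -0.63 (adjusted p = 0.338) and 2 members lower adjusted over the list alone. Cholesterol synthesis rose (median 0.22, 5 of 6 above 0, adjusted p = 0.0162, adjusted p = 0.453 with an estimated correlation), but was at -0.35 with normexp as first run. In the panel IGFBP2 was at 1.43 (adjusted p = 0.319) and did not pass.

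At day 50 in all 19 features passed in limma, 9 higher and 10 lower in runts, 3 of them with a symbol. An unadjusted limma p under 0.05 was reached by 2132 features, against 1434 by chance alone. The smallest adjusted p belonged to probes without a symbol, A_72_P255752 (-2.67, adjusted p = 3.92e-05) and A_72_P081691 (3.20, adjusted p = 9.36e-05). The level of A_72_P255752 in day 50 runts, -6.72 ± 0.34 (SD), lay below that of NR1I2 there (-6.19), which was not above background. The size of the A_72_P255752 difference is therefore uncertain. The complement median was -0.99 with slide as a block (adjusted p = 1.14e-06 by camera) and -1.08 within slides 4 to 9 (adjusted p = 1.48e-06 by camera). Within slides 1 to 3, which hold only 1 day 50 runt array (replicate 4), it was -0.86. The count of features was 0 with slide as a block, 1 within slides 4 to 9, 5 without control replicate 1 and 65 without runt replicate 3. The Kupffer, xenobiotic, cell cycle and amino acid catabolism calls ended with slide as a block (camera adjusted p = 0.864, 0.583, 0.254 and 0.189). Their medians were then 0.045, -0.005, -0.185 and -0.38, so amino acid catabolism lost its call but not its fall. Of the 6 lists only complement and xenobiotic kept their call with each array of day 50 left out. The xenobiotic call also ended with the stricter filter, which kept 15 members (median 0.0036, camera adjusted p = 0.392).

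At day 70 the granulocyte list was lower in runts (median -0.47, 13 of 14 below 0, adjusted p = 8.58e-05, adjusted p = 0.822 with an estimated correlation), with the anti-inflammatory protein ANXA1 at -0.55 and 0 of 14 members passing. No gene passed. Those with the smallest p were threonine dehydrogenase, TDH (-1.03, SE 0.28), SAA3 (-1.63, SE 0.51), the nuclear receptor NR4A3 (at least 1.198-fold), SULT1E1 (-2.03, SE 0.72) and GHR (0.82, SE 0.29), each at adjusted p = 1. NR4A3 was above background on 3 runt and 0 control arrays, SULT1E1 on 3 of each, and GHR on 4 runt and 2 control arrays. In limma 0 features passed and 522 had an unadjusted limma p under 0.05, fewer than the 1434 that chance alone would give. The granulocyte call ended without day 70 control replicate 4 (adjusted p = 0.0591) and within slides 1 to 3 (adjusted p = 0.683). The count of lists was 2 with slide as a block and 3 within slides 1 to 3.

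At day 110 the erythroid, cell cycle and granulocyte lists were lower in runts against other genes by camera, and each call ended when 1 array was left out. The erythroid list fell (median -0.71, 5 of 5 below 0, adjusted p = 0.000100, adjusted p = 0.389 with an estimated correlation), with TFRC at -0.91 (adjusted p = 0.848, above background on 2 runt arrays) and 1 member lower adjusted over the list alone. Its score differed by -0.63 (exact p = 0.229, adjusted p = 0.914). The cell cycle list fell (median -0.28, 9 of 10 below 0, adjusted p = 0.00301, adjusted p = 0.669 with an estimated correlation), with CCNB1 at -0.45. Granulocyte genes fell (median -0.43, 11 of 14 below 0, adjusted p = 0.00416, adjusted p = 0.669 with an estimated correlation), with PR39 at -1.07. Without runt replicate 3 the granulocyte median was -0.21 and was not called (adjusted p = 0.264). The amino acid and unfolded protein stress list rose (median 0.22, 6 of 8 above 0, adjusted p = 0.0433, adjusted p = 0.430 with an estimated correlation), with the stress regulator ATF4 at 0.55 (adjusted p = 0.901). This call ended with the replicate block (adjusted p = 0.109), and with quantile normalization, normexp, the stricter filter, slide as a block and the slide set at adjusted p = 0.134, 0.483, 0.0717, 0.571 and 0.0782. The stress median was 0.22 with the stricter filter, 0.18 with quantile normalization, 0.13 with slide as a block and 0.12 with normexp. Of these lists 0 members passed over all genes. Named genes with the smallest p did not pass, among them the small GTPase DIRAS2 (3.07, SE 0.61, adjusted p = 0.127, above background on 1 control array) and cyclin D2, CCND2 (1.26, SE 0.26, adjusted p = 0.129, but adjusted p = 0.0115 with the replicate block, which passes). Next came the spermadhesin PSP-I (2.14, SE 0.51, adjusted p = 0.321) and PLA2G1B (1.96, SE 0.49, adjusted p = 0.393). In limma 4 features without a symbol passed, A_72_P437114 (2.96) and A_72_P400008 (2.44) higher and A_72_P208502 (-3.03) and A_72_P050291 (-3.71) lower in runts. An unadjusted limma p under 0.05 was reached by 1268 features, fewer than the 1434 that chance alone would give. The erythroid median was 0.16 within slides 1 to 3 (adjusted p = 0.655), where the cell cycle median was 0.25, and without control replicate 3 the erythroid and cell cycle medians were -0.33 and -0.02 (adjusted p = 0.113 and 0.98) and only 1 list was called. The count of features was 0 with slide as a block and 1 without control replicate 4.

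**Figure D4:**
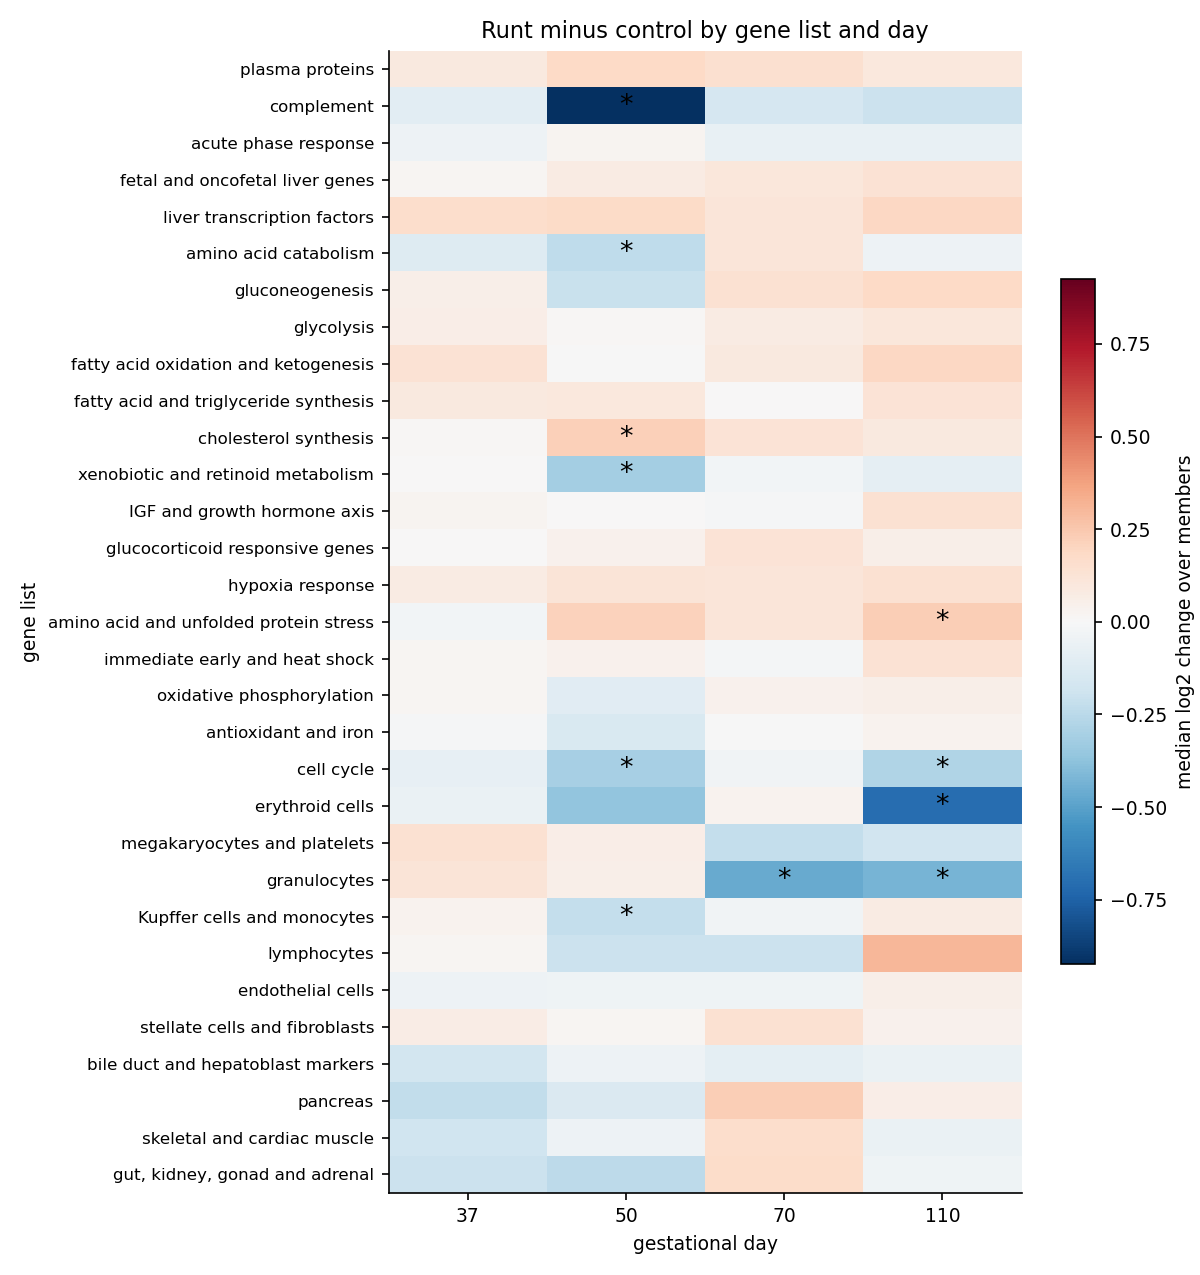
Median log2 difference between runts and controls over the members of the 31 tested gene lists at each gestational day, with an asterisk for a camera adjusted p under 0.05. The complement list at day 50 (-0.92) was the lowest value with a call, and 0, 6, 1 and 4 lists were called at days 37, 50, 70 and 110.

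Averaged over the 4 days, 5 genes with a symbol were lower and 9 higher in runts. SULT1E1 (NM_213992) was lower in runts (-2.08, SE 0.36, adjusted p = 0.0158), at -1.63, -2.54, -2.03 and -2.11 on the successive days. ALB was lower too (-1.53, SE 0.29, adjusted p = 0.0227), at -2.54, -2.73, -0.36 and -0.50. SAA3 (-1.28, adjusted p = 0.0249), LBP (-0.99, adjusted p = 0.0227) and TDH (-0.73, adjusted p = 0.0227) were also lower. PSP-I (NM_213837) was higher (1.46, SE 0.25, adjusted p = 0.0158), as were the mitochondrial thiolase ACAA2 (0.62, adjusted p = 0.0488), and CCND2 (0.61, adjusted p = 0.0353, while its other probe was at 0.44, adjusted p = 0.285, and did not pass). The kisspeptin receptor KISS1R (0.50, adjusted p = 0.0227) and PEMT, which makes phosphatidylcholine (0.46, adjusted p = 0.0486), were higher as well. Singled out after their values were seen, the other named genes that passed were SPMI (2.60), the spermadhesin AQN-1 (1.64), DIRAS2 and the steroid dehydrogenase HSD17B2 (0.43), all higher. SPMI and AQN-1 were above background on 0 of the 4 day 110 control arrays, which enter these means. DIRAS2 was above background on 0 of 8 arrays at day 37, 1 of 8 at day 50, 1 of 8 at day 70 and 1 of 4 control arrays at day 110, so no mean is given for it. IGFBP2 (0.84, adjusted p = 0.116), AFP (0.19, adjusted p = 0.794), IGF1 (-0.21, adjusted p = 0.640, but 0.37 with normexp as first run) and IGF2 (0.17, adjusted p = 0.661) did not pass.

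The complement list was lower over the 4 days (median -0.33, 14 of 17 below 0, adjusted p = 2.14e-07, adjusted p = 0.0606 with an estimated correlation), with 8 members lower adjusted over the list alone and C8B at -0.85 (adjusted p = 0.0693). The cell cycle list fell (median -0.16, 10 of 10 below 0, adjusted p = 0.00356, adjusted p = 0.514 with an estimated correlation). The erythroid list fell (-0.26, 5 of 5 below 0, adjusted p = 0.0175, adjusted p = 0.514 with an estimated correlation), as did the granulocyte list (-0.16, 14 of 14 below 0, adjusted p = 0.0175, adjusted p = 0.569 with an estimated correlation). Haptoglobin, HP, a liver gene in the granulocyte list, was at -0.57 (adjusted p = 0.139). The xenobiotic list fell (median -0.09, 16 of 24 below 0, adjusted p = 0.0175, adjusted p = 0.400 with an estimated correlation), SULT1E1 being the 1 member that passed and 6 passing adjusted over the list alone. Plasma proteins rose against other genes (median 0.12, 21 of 24 above 0, adjusted p = 0.00678, adjusted p = 0.514 with an estimated correlation) while ALB, the 1 member that passed, was lower. Liver transcription factors (median 0.15, 11 of 13 above 0, adjusted p = 0.0175, adjusted p = 0.233 with an estimated correlation) rose. Stress genes rose (median 0.19, 6 of 8 above 0, adjusted p = 0.0325, adjusted p = 0.400 with an estimated correlation), XBP1 being at 0.21 (adjusted p = 0.201), while another of its probes was at 0.30 and passed (adjusted p = 0.0493). With normexp as first run, which moved the median of all genes by 0.19, these 3 lists turned against other genes, to medians of -0.19, 0.10 and -0.11. With quantile normalization all 3 calls ended, at medians of 0.034 (adjusted p = 0.780), 0.14 (adjusted p = 0.0567) and 0.16 (adjusted p = 0.297), and the stress call also ended with the replicate block (adjusted p = 0.122) and the stricter filter (adjusted p = 0.0828). Calls of the xenobiotic, stress, erythroid and granulocyte lists also ended with single arrays left out. The xenobiotic call ended with the stricter filter as well (median -0.025, camera adjusted p = 0.286). In all 70 features passed, 48 higher and 22 lower in runts, 14 with a symbol (9 higher and 5 lower). The count was 1 with slide as a block, 0 within slides 1 to 3 and 23 within slides 4 to 9, and it ranged from 36 without day 37 runt replicate 4 to 157 without day 37 runt replicate 3.

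Whether the runt effect depended on the day was tested directly. The score of the complement list differed in its runt effect between days, at -0.12, -0.89, -0.20 and -0.20 for days 37, 50, 70 and 110 (SE 0.13, adjusted p = 0.0220 over 31 lists by limma). For the other 30 lists the adjusted p was 0.997. Only the unnamed probe A_72_P255752 passed among single features (adjusted p = 0.0222), at 0.05, -2.67, -0.49 and 0.05 (SE 0.30). Its level in day 50 runts, -6.72 ± 0.34 (SD), lay below that of NR1I2 in that group (-6.19), which was not above background. The size of its day 50 difference is therefore uncertain. An unadjusted limma p under 0.05 was reached by 439 features, fewer than the 1434 that chance alone would give. The named genes with the smallest p did not pass (adjusted p = 1 each), namely NR1I2 (-0.73 and -0.11 at days 70 and 110, not above background in either group at day 37 or in runts at day 50), LBP (-0.70, -2.44, -0.56 and -0.27), and MASP2 (-0.10, -1.53, 0.20 and 0.09). The others were SERPINA3-2, GLUL, the chemokine receptor CCR1, DIRAS2, TMEM87A, NPPC and NR4A3. The count of features was 0 with slide as a block and 0 within either slide set.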

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

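The tests of loss of blood-forming cells, of fewer hepatocytes, of a delay at day 50 and of blood-forming cells of all kinds, the granulocyte score with arrays left out and the splits of the mean that part the pairs were chosen only after the results were seen, as were the slide set, the removal of an alias from the granulocyte list and the definition of probes that are on or off.

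The complement list differed in its runt effect between days (adjusted p = 0.0220 by limma), with a score difference of -0.89 at day 50 against -0.12 to -0.20 at the other days, and 15 of its 17 genes below 0 at that day. A slide effect is argued against, since the score difference was -0.88 (SE 0.14) with the slide set as a block. Day 50 runt replicates 1, 2 and 3 were among the arrays whose spots of high local background distorted normexp. With normexp as first run the complement median was -0.95 (adjusted p = 0.000110 by camera). Fewer hepatocytes would lower plasma protein mRNAs as much. Complement fell more than their score (0.06) by -0.96 (SE 0.16, exact permutation p = 0.0286, the smallest possible), but ALB among them was at -2.73. A developmental delay may still contribute. Across genes, which are not independent, the day 50 runt effect correlated with the control change from day 37 to day 70 at r = 0.234 (rho = 0.330). A delay would give a negative value, but other labelings of the 8 arrays reached -0.393 and 0.886 of them gave a value as low. The test excluded nothing, although its written bound was met. A loss of complement expression by hepatocytes of runts near day 50 stays a hypothesis, tested on the data it was found in.

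The liver function lists were higher at day 110 than at day 37 in controls. Loss of blood-forming cells alone would raise all hepatocyte transcripts by about the same amount, but complement rose more than plasma proteins by 1.58 (SE 0.16, exact permutation p = 0.0286). Array scaling stays open: the complement median was 2.01 with quantile normalization, whose mark the authors' table bears, and normexp (1.88) corrects background. A changing mix of cells together with maturation of hepatocytes remains a candidate explanation that bulk tissue cannot resolve. Array position on the slide went with day and cannot be told apart from it either.

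The erythroid list was lower in runts at day 110 by camera (median -0.71). It was not called with an estimated correlation (adjusted p = 0.389), and the exact test of its score gave p = 0.229. The difference of scores was -0.59 (SE 0.26) with the slide set as a block, so slide set alone is argued against, but it shrank to -0.28 without day 110 control replicate 3, and 1 array may thus account for much of it. Fewer blood-forming cells of all kinds stays open: granulocytes were at -0.36 (SE 0.43) and megakaryocytes at -0.15 (SE 0.15), both within 2 SE of 0, which excludes neither a fall nor its absence, and granulocytes were at -0.07 without day 110 runt replicate 3.

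The probe A_72_P255752 differed in its runt effect between days (adjusted p = 0.0222 by limma), being lower in runts at day 50. Its level there was -6.72, below that of NR1I2, which was not above background in that group, so the size of the effect is uncertain. The other values stood apart from the rest of their group of 4, which chance alone brings about for about 1 group in 20. This was so in 12 of 184 groups, or 6.52%. Outlier spots numbered 234 on day 70 control replicate 4 against 2 to 14 on its group, and 5 on day 110 runt replicate 4 against 6 on each of the others. DLK1 was at 1.61 in day 70 control replicate 1 (others 0.44 to 0.59). APOA4, an intestinal and hepatic apolipoprotein, was at 3.72 in day 50 runt replicate 2 (others -1.09 to -0.32) and at 4.61 in day 110 control replicate 3 (others 1.08 to 1.62). The complement score was 0.44 in day 50 runt replicate 2 (others 0.80 to 0.84), and the cholesterol synthesis score 2.76 in day 50 control replicate 3 (others 2.49). The xenobiotic score was 1.55 in day 70 runt replicate 3 (others 2.23 to 2.36), the granulocyte score 0.91 in day 110 runt replicate 3 (others 1.98 to 2.11) and the stress score 4.57 in day 70 runt replicate 2 (others 4.37 to 4.39). The erythroid score was 4.43 in day 50 control replicate 4 (others 4.22 to 4.25), and the score of liver transcription factors 1.00 in day 70 control replicate 4 (others 1.26 to 1.30).

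Other splits of the same arrays into groups of the same sizes were run for every count. Only the real split gave as many genes between days 37 and 50 (979, highest other 1) and days 50 and 70 (2204, highest other 4, a split that follows the slide set). The same held between days 70 and 110 (3565, highest other 859), between days 37 and 110 (8402, highest other 1112) and for runts at day 50 (19, highest other 1). Each of these shares is 1 of 35, the smallest possible. For the mean runt effect (70, highest other 1539) it was 2 of 100. The shares were not adjusted for the number of counts tested. If the numbers pair littermates at day 50, 8 of the 35 splits part as many pairs, and 1 of these 8, the real one, gave as many genes. Such a share does not exclude chance there. The splits drawn for the mean part at most 14 of the 16 pairs of one number and the real one all 16, but among 100 splits that part every pair at days 37 and 110 the highest other count of genes was 1, with 1 of 100 as large, while 7 of 100 gave as many lists. For runts at days 37 and 70 the real count of genes was 0, so every split gave as many (35 of 35 each, highest other 18 and 9) and chance was not tested. It was not excluded at day 110 (4, highest other 802, 9 of 35) or for the difference between days (1, highest other 310, 19 of 100). Splits with counts of 802, 1539 and 310, several times the real count, point to a structure of the samples, whose source was not tested. The split with 802 did not follow the slide set. For lists, chance was not excluded between days 37 and 50 (3, highest other 9, 14 of 35), days 50 and 70 (13, highest other 14, 4 of 35), days 70 and 110 (12, highest other 12, 3 of 35) and days 37 and 110 (14, highest other 15, 3 of 35, with 1 of the 2 highest splits following the slide set), nor for runts at day 50 (6, highest other 9, 4 of 35), day 70 (1, highest other 6, 32 of 35), day 110 (4, highest other 10, 10 of 35) or the mean (8, highest other 9, 6 of 100). At day 37 the real count of lists was 0 and every split gave as many (highest other 8). For the complement list itself the real median of -0.92 lay outside the -0.67 to 0.59 of the other splits. Where the numbers pair the fetuses, 8 of the 35 splits part as many pairs, and among them as large a count at day 110 was given by 2 for genes and 5 for lists, while the remaining splits put littermates on one side.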

How the results depend on the processing

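The slide set, fits within slides 1 to 3 and 4 to 9, both rules that set spots aside before normexp (the later rule chosen after the counts of the earlier were seen), the older granulocyte list and the fit without the array alone on its slide were chosen only after the results were seen. Signal over background limits what could be seen, since 51.3% to 69.4% of spots were well above background, and simulated shifts at day 50 were found for 7 of 67 genes at 1.5-fold, 32 of 67 at 2-fold and 48 of 66 at 4-fold, with 5 wrong of 92 calls. For the mean of the 4 days 42 of 67, 55 of 67 and 66 of 66 were found, with 8 wrong of 171, and between days 37 and 50 it was 1 of 67, 22 of 67 and 58 of 66, with 6 wrong of 87. A simulated shift of -0.5 in the complement list at day 50 was called (adjusted p = 1.88e-05 by camera) with 0 other lists. The simulated noise was drawn separately for each gene, without correlation between genes and without slide or litter effects. The rates of wrong calls therefore need not hold for the real arrays. Normexp as first run moved the median of all genes by up to 0.41 (runts at day 50, and 0.19 for the mean), quantile normalization by up to 0.07. On 6 runt arrays 1 to 33 spots had a local background more than 100 above their signal, and after normexp their 10th percentile lay at -1.50 to -0.15 against -2.63 to -1.80 on the other 26, so these spots caused its large runt counts. With them set aside it was -2.32 to -2.10. Day 50 runt replicates 1, 2 and 3 were among the 6 arrays. On replicate 1, alone on its slide, 10218 spots had a local background above their signal, 4 of them by more than 100.

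Of 61 list results, 54 kept direction and call with quantile normalization, 52 with normexp, 50 with slide as a block, 58 with the replicate block, 11 with an estimated correlation and 42 by fry. Of 253 gene results 240 kept both with quantile normalization, 186 with normexp, 235 with slide as a block, 248 with the replicate block and 240 with the authors' table. Of the 19 features called at day 50, 18 were shared with quantile normalization and 15 with the replicate block, and of the 70 for the mean 65 were shared with the replicate block. Where no cause is given below, the cause was not tested.

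Counts of genes between days 37 and 50 (979) became 82 with normexp, 142 and 149 with its 2 later rules, 437 with the stricter filter, which tests fewer genes, and with fewer arrays 0 within slides 1 to 3 and 152 within slides 4 to 9. Between days 50 and 70 (2204) they became 439, 528, 5.4e+02, 1031, 1 and 498 in the same order. Between days 70 and 110 (3565) they became 1545, 1586, 1592 and 1973, and 1827 within slides 1 to 3. Between days 37 and 110 (8402) they became 4018, 4058, 4052 and 5048, and 5310 within slides 1 to 3.

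For runts at day 50 the count of 19 became 46 with quantile normalization, 17060 with normexp (12659 higher and 4401 lower), 36 with its earlier rule, 35 with the stricter filter, 0 with slide as a block, 33 with the slide set, 51 with the replicate block, 2 with only the arrays compared, 209 with array weights, 36 with trend and robust, 40 with the authors' table, 0 and 1 within slides 1 to 3 and 4 to 9, and 6 without the array alone on its slide. At day 70 the count of 0 became 1 with the replicate block. At day 110 the count of 4 became 2 with normexp, 2 with the stricter filter, 0 with slide as a block, 1 with only the arrays compared and 1 within slides 4 to 9. For the mean the 70 became 13927 with normexp (11929 higher and 1998 lower), 33 with its earlier rule, 44 without a filter, 111 with the stricter filter, 1 and 176 with slide as a fixed and a random block, 186 with the replicate block, 159 with array weights, 120 with trend and robust, 0 and 23 within slides 1 to 3 and 4 to 9, and 45 without the array alone on its slide. The 1 feature with an effect differing between days became 0 with quantile normalization, normexp and both its rules, the stricter filter, slide as a fixed or random block, trend and robust, the authors' table, the slide set, within either set and without the array alone on its slide. At day 37 the count was 0 in limma under every alternative but 1 array left out.

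Counts of lists between days 37 and 50 (3) became 0 with an estimated correlation, 1 by fry, 7 with normexp, 7 and 5 with its rules and 0 with the older granulocyte list. Between days 50 and 70 (13) they became 1 with an estimated correlation and 23 by fry, between days 70 and 110 (12) 3 with an estimated correlation, and between days 37 and 110 (14) 6 with an estimated correlation, 23 by fry and 8 with the stricter filter. For runts at day 37 the 0 became 7 with normexp, 2 with slide as a block, 1 with the replicate block, 2 with the slide set and 3 within slides 4 to 9. At day 50 the 6 became 1 with an estimated correlation, 1 by fry, 16 with normexp and 10 with the replicate block. At day 70 the 1 became 0 with an estimated correlation, 0 by fry, 3 with quantile normalization, 21 with normexp, 5 with each of its rules, 3 with the stricter filter, 2 with slide as a block, 4 with the replicate block and 3 within slides 1 to 3. At day 110 the 4 became 0 with an estimated correlation, 0 by fry, 7 with slide as a block and 0 within slides 1 to 3. For the mean the 8 became 0 with an estimated correlation, 2 by fry, 17 with normexp, 5 with the stricter filter and 1 within slides 1 to 3.

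With 1 array left out at a time, counts of genes ran from 622 (without day 37 control replicate 2) to 1062 between days 37 and 50, 1727 to 2761 between days 50 and 70, 3198 to 3707 between days 70 and 110 and 7759 to 8795 between days 37 and 110. For runts they ran from 0 to 2 (without day 37 runt replicate 3), 5 (without day 50 control replicate 1) to 65 (without day 50 runt replicate 3), 0 to 1 (without day 70 control replicate 3) and 1 (without day 110 control replicate 4) to 11 (without day 110 control replicate 1) at the successive days. They ran from 36 (without day 37 runt replicate 4) to 157 (without day 37 runt replicate 3) for the mean and from 0 to 2 for the difference between days. More than a 1.5-fold move was seen for 5 of 8 arrays at day 50, 5 of 8 at day 110, 12 of 32 for the mean and 7 of 32 for the difference. Counts of lists ran from 0 (without day 37 control replicate 3) to 6 (without day 37 control replicate 1), 11 to 15, 10 to 12 and 12 to 15 over the control intervals, and from 0 to 2, 2 (without day 50 control replicate 4) to 8, 0 to 3, 1 (without day 110 control replicate 3) to 5 and 7 to 11 for runts and their mean.

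Where either fit made a call, 11 directions turned, the cause untested beyond the background spots named. With the stricter filter lymphocytes were at 0.18 between days 50 and 70 (down against other genes by camera, adjusted p = 0.889) and at -0.32 between days 37 and 110. Within slides 1 to 3 the cell cycle list was at 0.25 in day 110 runts. With normexp as first run cholesterol synthesis was at -0.35, TMEM87A at -0.032, NR1I2 at 0.94 and IGF1 at 0.82 in day 50 runts, and for the mean plasma proteins were at -0.19, liver transcription factors at 0.10 (down against other genes), stress genes at -0.11 and IGF1 at 0.37.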

Other observations

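The definition of probes that are on or off, the choice of the spermadhesin genes and their grouping were made only after the data had been seen, and the delay tests at days 37, 70 and 110 were set beforehand.

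PSP-I, SPMI and AQN-1, genes of the seminal plasma spermadhesins, secreted proteins best known from the boar's accessory glands, were detected in fetal liver, while a further one, PSP-II, did not pass for the mean runt effect (0.70, adjusted p = 0.268). PSP-I was higher by 0.91, 2.39, 0.42 and 2.14 at days 37, 50, 70 and 110, SPMI by 1.37, 3.44 and 1.94 and AQN-1 by 0.50, 2.78 and 1.52 at days 37, 50 and 70, each passing for the mean of the 4 days (adjusted p = 0.0158, 0.0317 and 0.0373 by limma) and none on a single day. At day 110 SPMI and AQN-1 were above background on 0 of 4 control and 2 of 4 runt arrays each, so no difference is given for that day, although their means over the days include it. AQN-1 was above background on 1 and 2 of the 4 control arrays at days 50 and 70. These genes are close relatives, so 1 transcript can bind several of their probes, and they were not counted as independent.

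IGFBP2 lay above its control mean in runts on all 4 days (1.01, 1.43, 0.56 and 0.36), yet did not pass for the mean (0.84, SE 0.23, adjusted p = 0.116 by limma). A further probe of DLK1 gave -4.74 between days 70 and 110 and passed, while the probe that stood for the gene did not, so its probes differ.

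A set of 27 probes was either on or off, with a gap of at least 3 on the log2 scale and both states in at least 4 groups. Of these, 12 were on together in 18 arrays and 6 others on in exactly the 14 remaining arrays, with gaps of 3.47 to 7.44 and 5.29 to 7.86 (A_72_P124796 and A_72_P057546 are examples). The 18 arrays were 4, 3, 2, 3, 2, 1, 2 and 1 of the control and runt groups of the successive days. RIPPLY3 (3 probes) and the antimicrobial peptide gene PMAP-36 (gap 5.77) were on in 8 arrays each. The probe A_72_P424229 was on in 24 arrays and off in all 4 day 70 runts. Whether these probes differ between runts and controls stays open, since the lowest adjusted p was 0.887 (Fisher's exact test over 16 runts and 16 controls, without regard to day). The bound written beforehand read this as exclusion, which a missed threshold does not give. Fetal sex, which the labels do not give, is a candidate explanation for the complementary sets that was not tested, and it was not used as a covariate.

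If runts lagged behind in development, their differences would run against the control time course. Across genes, which are not independent, the runt effect at day 37 correlated with the control change from day 50 to day 110 at r = 0.215 (rho = 0.267). This was the highest of the 70 labelings and opposite in sign to a delay. Where the numbers pair littermates, only 8 of the 35 splits, each with its mirror, part as many pairs at day 37. Ranking highest among so few, with slide not in the test, does not exclude a delay. At day 70 it was 0.0659 (rho = 0.0883) and at day 110 0.0614 (rho = 0.0795), with 0.671 of the labelings as low at both days and lowest values of -0.285 for each, so a delay may still be present there. The bound written beforehand read any value above 0 as exclusion, which the spread of the other labelings does not bear out. These 4 correlations, with that of day 50, were all that were computed.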
